A study of Homo sapiens with 35 samples.

How the data were processed

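RNA-seq and ATAC-seq were measured in AsPC-1, an established human pancreatic ductal adenocarcinoma cell line, after knockdown of ODC1, OAT or ARG2 with a short hairpin RNA (a construct that lowers the mRNA of the gene it targets). Each of the 3 targets had 2 hairpins, called #1 and #2 here, and the control was a scrambled hairpin, shScr. Per the labels, cells were kept for 24 h in medium with 0.1% serum and 100 ng/ml IGF-1. RNA-seq (polyA-selected) had 3 biological replicates in each of 7 groups, 21 libraries in all. ATAC-seq, which reads open chromatin, had 2 biological replicates in each of 7 groups, 14 libraries in all.

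The authors deposited 1 table of raw read counts for 19930 protein-coding genes and 1 list of peaks per ATAC-seq library. The submitters' processing notes name STAR 2.7.8a, HTSeq 0.13.5 and DESeq2 for RNA-seq, Bowtie2 2.4.2 and MACS2 for ATAC-seq, and the genome build GRCh38. They give no version of DESeq2 or MACS2, no strandedness, no annotation release, no MACS2 options, and no word on duplicates or the shift for the transposase. The deposited peak lists hold the fold enrichment over the local background and the -log10 q value of each peak. The lowest -log10 q in a list lay between 2.00 and 2.03. Neither quantity was compared between libraries as a signal, since each list has its own background. Total counts per RNA-seq library ran from 17661719 to 34878402 and are the depth behind each expression value. No read depth of the ATAC-seq libraries was deposited, so the depth there is unknown.

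Gene expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 7 groups, with a minimum count of 10 and a minimum total of 15, which left 12726 genes. Normalization was TMM, and a single robust quasi-likelihood fit of all 21 libraries, with 14 residual degrees of freedom, had 1 coefficient per group. Tests were 2-sided, and p was adjusted over the 12726 genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, with no minimum fold change. A gene is said to have risen or fallen with a target only when both of its hairpins called it with the same sign. Differences between targets were tested as the mean of 1 target's hairpins minus the mean of the other's, and a gene counted only when all 4 hairpin-by-hairpin differences had that sign. Levels are CPM, the counts of a gene scaled to a common library size with TMM-scaled library totals, given with the SD over 3 libraries, and the SE of a log2 fold change was taken from its F statistic. The p-values measure the spread between biological replicates of a hairpin in 1 cell line, not the spread between hairpins.

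Gene lists were written from general knowledge. The 27 lists hold 829 entries, of which 824 were in the table and 721 were tested. They cover polyamine metabolism, arginine and ornithine metabolism, DNA replication and G1/S, mitosis, histones, MYC and ribosome biogenesis, ribosomal proteins, p53 targets, the ATF4 stress response, the unfolded protein response, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, the nuclear respiratory chain, transcripts of the mitochondrial genome, the interferon response, NF-kB and inflammation, the MAPK early response, NRF2 and redox, lysosome and autophagy, epithelial-mesenchymal transition, classical epithelial genes, basal-like genes, chromatin regulators, and markers of fibroblasts, immune cells and endothelial cells. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) of the mean of both hairpins, 2-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 81 tests. Camera asks whether a list moved against all other genes, so its direction can differ from the sign of the list's mean. The test was repeated with a correlation estimated from the data.

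Fewer genes and regions are named than the rule below gives. Those named follow that rule. It takes the 3 targets in every group, and per target the 10 genes that rose and the 10 that fell with the largest smaller fold change of both hairpins, among genes with a mean log2 CPM of at least 2. It also takes 6 up and 6 down among genes called alike in all 4 ODC1 and OAT hairpins and in all 6 hairpins, and the 5 highest and 5 lowest for each difference between targets. From the polyamine and arginine lists it takes every called member, and from each other list up to 4 in each direction. For ATAC-seq it takes the 3 lost and 3 gained regions per target with the highest mean rank of -log10 q, and those within 1 kb of a named gene. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined, except that gene ends later took the place of transcription start sites.

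Correlations across genes carry no p, since genes are not independent replicates. They were set beside 100 simulations of unchanged groups that share the shScr libraries, drawn from the fitted means and dispersions, and calls were counted in 20 simulated fits. The fit was also tested on simulated data for shODC1 #1 against shScr. At a true change of 1.2, 1.5, 2 and 4-fold, 30%, 66%, 78% and 90% of 50 genes each were called with the right sign, and 7.69% of the calls were false. The share called with both hairpins was 18%, 62%, 76% and 88%.

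ATAC-seq peaks of the 14 libraries were merged where they overlapped by at least 1 bp. A region was lost with a target when both shScr libraries and none of the target's 4 libraries held a peak there, and gained when all 4 and neither shScr library did. Counts were compared with the other splits of the same 6 libraries into 2 and 4, which number 15 in all, so no share under 0.0667 can arise. Peak numbers were compared by an exact permutation test, 2-sided, with the same limit. Similarity of libraries was the Jaccard index in base pairs, tested by 100000 permutations of the group labels, 1-sided. Regions were joined to expression within 1 kb of either end of a gene with Fisher's exact test, 2-sided, adjusted over 6 tests by the Benjamini-Hochberg method. The gene table gives no strand, hence no transcription start site, so both gene ends were used in place of it, and 12618 of the 12726 tested genes (99.2%) could be placed. The background was the genes tested in RNA-seq with a merged region within that distance.

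The alternatives were DESeq2 1.42.0 with its Wald test, DESeq2 size factors, no normalization factors, no filter on low counts, a mean CPM of at least 1, a log2 fold change of at least 1, a replicate block, only the groups compared, each library left out in turn, and 3 outlying libraries (shScr replicate 3, shOAT #1 replicate 2 and shARG2 #2 replicate 3) left out together. For lists they were an estimated correlation, a prior count of 0.5, the replicate block, the same left-out libraries, and each hairpin alone. For correlations they were each pair of hairpins, genes with a mean CPM of at least 10, and the shScr libraries divided between the targets, 1 for one and 2 for the other, as the mean of 6 arrangements. For ATAC-seq they were a -log10 q of at least 5, the 61785 strongest peaks of each library, main chromosomes only, peaks that cover at least 50% of a region, at most 1 of 4 or at least 3 of 4 libraries, each library left out in turn, and a distance of 5 kb. Statistics outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9. No deposited library was left out.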

Results

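RNA-seq and ATAC-seq were compared in AsPC-1 pancreatic cancer cells after knockdown of ODC1, OAT or ARG2, each with 2 hairpins, and with the scrambled control shScr. ARG2 encodes an enzyme that makes ornithine from arginine, OAT encodes one that interconverts ornithine and a precursor of proline and glutamate, and ODC1 encodes the enzyme that turns ornithine into the polyamine putrescine. RNA-seq had 3 libraries in each of 7 groups and ATAC-seq had 2 in each of 7. Total RNA-seq counts per library ran from 28206028 to 29366097 with shScr, 25944751 to 33322497 with the ODC1 hairpins, 25284440 to 33211831 with the OAT hairpins and 17661719 to 34878402 with the ARG2 hairpins. ATAC-seq libraries held 61785 to 77836 peaks, and their read depth is unknown. Values of the hairpins of a target are given in the order #1 and #2, every group mean of expression is over 3 libraries, and fold changes are log2 against shScr unless another group is named.

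The first question was whether each hairpin lowered its target. ODC1 (chromosome 2, 10439968 to 10448327) fell from 272 ± 3.28 CPM (SD) in shScr to 57.2 ± 1.63 and 96.5 ± 1.60, so that 21.1% and 35.5% of the transcript remained. OAT (chromosome 10, 124397303 to 124418923) fell from 42.8 ± 2.89 to 2.85 ± 0.444 and 4.88 ± 0.738 CPM, which left 6.66% and 11.4%. ARG2 (chromosome 14, 67619920 to 67651708) was near the detection limit in every group, at 0.657 ± 0.270 CPM in shScr and 0.183 ± 0.106 and 0.30 ± 0.282 after its own knockdown. In edgeR the changes were -2.25 ± 0.05 (SE; adjusted p = 1.53e-21) and -1.49 ± 0.04 (adjusted p = 1.12e-17) for ODC1, and -3.91 ± 0.11 (adjusted p = 6.56e-19) and -3.12 ± 0.10 (adjusted p = 7.64e-18) for OAT. For ARG2 they were -1.76 ± 0.57 (adjusted p = 0.0192) and -1.26 ± 0.57 (adjusted p = 0.102), so only hairpin #1 passed. ARG2 rested on 13 to 27 counts in a shScr library and 2 to 11 in a shARG2 library, and 27.9% and 45.7% remained. Leaving out shScr replicate 1 ended the call of shARG2 #1 (-1.39, adjusted p = 0.104), as did leaving out its replicate 3 (-1.43, adjusted p = 0.0887). Leaving out shARG2 #2 replicate 3 made shARG2 #2 pass (-2.21, adjusted p = 0.0119).

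**Figure D1:**
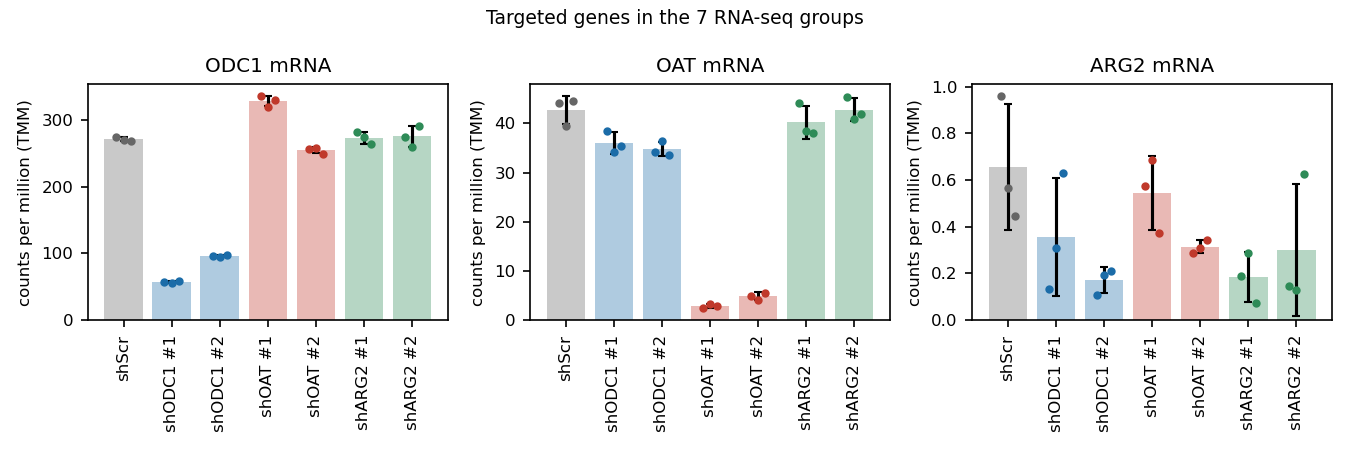
Levels of ODC1, OAT and ARG2 in CPM in the 7 groups, with bars for the mean, error bars for the SD and points for single libraries (3 per group). ODC1 and OAT were lowest with their own hairpins, at 57.2 and 2.85 CPM with hairpin #1, while ARG2 was at 0.657 CPM in the control.

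The targets also moved with each other's hairpins. ODC1 rose to 328 ± 8.04 CPM with shOAT #1 (0.27, adjusted p = 8.11e-06 in edgeR) and was at 255 ± 4.65 CPM with shOAT #2 (-0.09, adjusted p = 0.0668), a pair of values with opposite signs. Without shScr replicate 2 the second of these passed (-0.11, adjusted p = 0.0486). With the ARG2 hairpins ODC1 stood at 273 ± 9.01 and 275 ± 15.2 CPM (0.01 and 0.02, adjusted p = 0.894 and 0.772). OAT fell to 36.0 ± 2.15 CPM with shODC1 #1 (-0.25, adjusted p = 0.0231) and to 34.8 ± 1.43 with shODC1 #2 (-0.30, adjusted p = 0.00955). The call with shODC1 #1 was lost without shScr replicate 1 (-0.24, adjusted p = 0.0616), without shScr replicate 3 (-0.22, adjusted p = 0.0672), without shODC1 #1 replicate 2 (-0.22, adjusted p = 0.0821) and without its replicate 3 (-0.25, adjusted p = 0.054). OAT did not pass with the ARG2 hairpins, at 40.2 ± 3.38 and 42.8 ± 2.34 CPM (adjusted p = 0.452 and 0.987). ARG2 did not pass with shODC1 #1 (-0.92, adjusted p = 0.162) or the OAT hairpins (-0.28 and -1.05, adjusted p = 0.668 and 0.0819). It fell to 0.171 ± 0.0555 CPM with shODC1 #2 (-1.92, adjusted p = 0.0151), a call lost without shScr replicate 1 (-1.55, adjusted p = 0.0948) or shODC1 #2 replicate 1 (-1.67, adjusted p = 0.0707).

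Knockdown of ODC1 was compared with shScr to find the genes that depend on the first enzyme of polyamine synthesis. AMD1, which encodes the enzyme that supplies the aminopropyl donor for spermidine and spermine, rose from 140 ± 4.05 to 318 ± 11.3 and 257 ± 2.86 CPM. OAZ1, whose protein antizyme targets ODC1 for degradation, fell from 386 ± 7.92 to 279 ± 16.8 and 250 ± 12.7 CPM. Other rises were in RFLNA, an organizer of actin bundles, from 5.19 ± 0.771 to 18.9 ± 1.28 and 18.7 ± 1.36 CPM, and in IGFL2, a secreted IGF-like factor, from 7.45 ± 0.982 to 34.2 ± 0.660 and 20.0 ± 1.34 CPM. CLDN3, a tight-junction claudin, fell from 173 ± 15.8 to 67.8 ± 4.96 and 67.4 ± 4.77 CPM, CTSS, a lysosomal protease, from 23.5 ± 0.760 to 7.64 ± 0.797 and 8.25 ± 0.988, and CHST2, a sulfotransferase, from 23.9 ± 1.61 to 4.47 ± 0.340 and 8.78 ± 0.289. In edgeR, AMD1 rose by 1.19 ± 0.04 (SE; adjusted p = 8.93e-16) and 0.88 ± 0.04 (adjusted p = 3.73e-13), and OAZ1 changed by -0.47 (adjusted p = 7.85e-07) and -0.63 (adjusted p = 1.50e-08). RFLNA rose by 1.87 ± 0.17 (adjusted p = 1.67e-08) and 1.85 ± 0.17 (adjusted p = 2.85e-08), and IGFL2 by 2.20 ± 0.10 (adjusted p = 1.33e-14) and 1.43 ± 0.10 (adjusted p = 6.71e-11). CLDN3 changed by -1.36 ± 0.07 (adjusted p = 7.33e-13) and -1.36 ± 0.07 (adjusted p = 1.69e-12), CTSS by -1.62 ± 0.10 (adjusted p = 6.39e-12) and -1.51 ± 0.10 (adjusted p = 3.85e-11), and CHST2 by -2.41 ± 0.11 (adjusted p = 3.48e-14) and -1.44 ± 0.11 (adjusted p = 1.91e-10). Also up was CBX6 (1.23 and 1.43), and also down were ADGRG5 (-2.15 and -1.62) and PRSS8 (-1.37 and -1.50). FOS, an early-response transcription factor, fell (-1.59 and -1.32), but without shScr replicate 3 its changes were -0.76 and -0.48. Hairpin #1 called 5104 genes (2577 up, 2527 down) and hairpin #2 called 3942 (1931 up, 2011 down). Both called 2418 genes with the same sign, 1231 up and 1187 down, of which 56 and 74 changed at least 2-fold with both. With no normalization factors both called 1075 up and 1351 down.

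Several cell-cycle transcripts rose with ODC1 knockdown. The mitotic genes CENPF (0.52 and 0.60), MKI67 (0.46 and 0.50), NEK2 (0.49 and 0.45) and KIF4A (0.36 and 0.37) rose, and among DNA replication genes TK1 (0.34 and 0.35) and E2F1 (0.27 and 0.37) rose while CDC6 fell (-0.25 and -0.25). The chromatin remodeler CHD7 (0.69 and 0.39) and the demethylase KDM5A (0.30 and 0.34) also rose. In the mitosis list 18 of 43 genes rose and 1 fell, with a mean of 0.18 (camera adjusted p = 3.31e-06; adjusted p = 0.281 with an estimated correlation). In the DNA replication list 12 of 45 rose and 1 fell, or 13 and 1 adjusted over the list alone, with a mean of 0.10 (adjusted p = 0.0426; adjusted p = 0.321 with an estimated correlation). Of the chromatin regulators 10 of 46 rose and 1 fell, with a mean of 0.15 (adjusted p = 0.0154; adjusted p = 0.473 with an estimated correlation). With hairpin #2 alone the DNA replication list did not pass (0.05, adjusted p = 0.483). The DNA replication list did not pass without shScr replicate 2 (adjusted p = 0.0594) or 3 (adjusted p = 0.0502), shODC1 #1 replicate 1 (adjusted p = 0.0503) or 3 (adjusted p = 0.0681), or shODC1 #2 replicate 3 (adjusted p = 0.0708), nor did the chromatin list without shScr replicate 1 (0.10, adjusted p = 0.0848). Among MYC and ribosome biogenesis genes 3 of 39 rose, GRWD1 among them (0.27 and 0.22), and none fell (mean 0.05, adjusted p = 0.237), with 3 up and 1 down adjusted over the list alone. edgeR called 0 of 54 ribosomal protein genes, against 1 up and 2 down at unadjusted p under 0.05 and 1 up and 1 down with DESeq2 (camera adjusted p = 0.924). It called 0 of 23 histone genes, with 0 at unadjusted p under 0.05 and 0 with DESeq2 (mean -0.07, camera adjusted p = 0.904). Where no other count is given, here and for every list that follows, the count adjusted over the list alone was the same.

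Several stress and nutrient genes fell with ODC1 knockdown. SLC7A11, which imports cystine, fell from 176 ± 9.10 to 76.5 ± 2.24 and 86.0 ± 3.88 CPM, and DDIT4, an inhibitor of mTORC1, from 253 ± 11.3 to 128 ± 1.15 and 122.8 ± 3.97 CPM. TRIB3 (-0.80 and -0.94) and CTH (-0.66 and -0.61), both ATF4 targets, fell too, as did the endoplasmic reticulum genes SEC24D (-0.67 and -0.62) and DNAJB9 (-0.33 and -0.66). Of the ATF4 list 12 of 29 genes fell and none rose, with a mean of -0.30 (camera adjusted p = 6.59e-06). Of the unfolded protein response list 10 of 24 fell and 1 rose, or 11 and 1 adjusted over the list alone, with a mean of -0.18 (adjusted p = 0.000414). The p53 targets CDKN1A (-0.30 and -0.74), CCNG1 (-0.48 and -0.41) and FAS (-0.48 and -1.15) fell and PLK2 rose (0.33 and 0.39), with 2 of 28 up and 5 down in that list (mean -0.09, adjusted p = 0.523). In arginine metabolism ASS1 (-0.52 and -0.65) and ASL (-0.30 and -0.34), which make arginine from citrulline, fell and PYCR3 rose (0.27 and 0.23), with 1 of 16 up and 4 down (mean -0.21, adjusted p = 0.128). The polyamine list held 1 rise, AMD1, and 4 falls among 21 genes, ODC1, OAZ1 and OAZ2 (-0.52 and -0.41) among them (mean -0.24, adjusted p = 0.118). The glutathione gene GCLM fell (-1.22 and -0.62), and the NRF2 and redox list had 2 of 26 up and 7 down (mean -0.14, adjusted p = 0.103; -0.16 and adjusted p = 0.0404 without shScr replicate 1).

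Several lipid synthesis genes fell with ODC1 knockdown. The desaturase gene FADS2 (-0.91 and -0.93) and the acetate-activating ACSS2 (-0.41 and -0.59) fell. In cholesterol metabolism HSD17B7 (-0.65 and -0.65), TM7SF2 (-0.82 and -0.55) and STARD4 (-0.51 and -0.69) fell. In the cholesterol list 14 of 25 genes fell and 1 rose, or 15 and 1 adjusted over the list alone, with a mean of -0.23 (camera adjusted p = 4.58e-05; adjusted p = 0.122 with an estimated correlation). In the fatty acid list 5 of 15 fell and none rose, or 6 adjusted over the list alone, with a mean of -0.24 (adjusted p = 0.00251; adjusted p = 0.169 with an estimated correlation), and the list did not pass with hairpin #1 alone (-0.17, adjusted p = 0.219). The glycolysis regulator PFKFB4 (-0.88 and -0.84) and ALDOC (-0.54 and -0.59) fell while the demethylase KDM3A rose (0.35 and 0.50), and the hypoxia and glycolysis list had 3 of 34 up and 7 down (mean -0.13, adjusted p = 0.233). NDUFS7 of complex I rose (0.30 and 0.26) among 3 of 42 respiratory chain genes, and none fell (mean 0.01, adjusted p = 0.904). edgeR called 0 of 13 transcripts of the mitochondrial genome, with 1 up at unadjusted p under 0.05 and 1 up with DESeq2 (mean -0.02, camera adjusted p = 0.904).

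Signalling and identity genes moved both ways with ODC1 knockdown. The RNA sensor IFIH1 (-1.46 and -0.85) and EPSTI1 (-0.60 and -0.77) fell and OAS1 (0.42 and 0.33) and OAS3 (0.52 and 0.22) rose. The early-response factors FOSL1 (-0.97 and -0.68) and JUNB (-0.61 and -0.52) fell, JUNB by -0.39 and -0.29 without shScr replicate 3. The urokinase gene PLAU (-1.26 and -0.87) and the protease MMP14 (-0.68 and -0.48) fell. The transcription factors GATA6 (0.67 and 0.52), FOXA1 (0.52 and 0.57) and ZEB1 (0.54 and 0.41) rose, whereas E-cadherin, CDH1, fell (-0.72 and -0.82). The lysosomal genes GAA (0.53 and 0.63) and CTSA (0.46 and 0.54) rose and WIPI1 fell (-1.26 and -0.64). The interferon list had 2 of 32 up and 4 down and a mean of -0.34 (camera adjusted p = 0.00231). Its mean was -0.67 with hairpin #1 (adjusted p = 5.37e-06) and -0.00418 with hairpin #2 (adjusted p = 0.952), a difference of -0.66 (adjusted p = 2.92e-08). The MAPK list had 1 of 30 up and 7 down (mean -0.21, adjusted p = 0.180), and passed without shScr replicate 1 (-0.32, adjusted p = 0.0119). In the lysosome list 5 of 31 rose and 9 fell, or 5 and 10 adjusted over the list alone (mean -0.17, adjusted p = 0.171). In the NF-kB list TNFAIP3 rose (0.34 and 0.42) and LIF (-0.38 and -0.27) and NFKBIA (-0.22 and -0.41) fell, with 1 of 23 up and 2 down (mean -0.18, adjusted p = 0.171). The epithelial-mesenchymal list had 4 of 22 up and 4 down (mean -0.06, adjusted p = 0.963), the classical epithelial list 5 of 34 up and 7 down (mean 0.17, adjusted p = 0.924) and the basal-like list 2 of 13 down and none up (mean -0.11, adjusted p = 0.204). Among markers of other cell types 1 of 7 fibroblast genes (mean 0.30, adjusted p = 0.476) and 1 of 3 immune genes, CD68 (0.33 and 0.23), rose (list mean -0.08, adjusted p = 0.904). edgeR called 0 of 3 endothelial genes, with 0 at unadjusted p under 0.05 and 0 with DESeq2 (mean 0.10, camera adjusted p = 0.852). Camera called 8 of the 27 lists, and the ATF4, unfolded protein response and interferon lists held with an estimated correlation (adjusted p = 0.0349, 0.0349 and 0.0232). The median, the mean and the test differed in sign for ribosomal proteins, classical epithelial genes and immune markers.

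**Figure D2:**
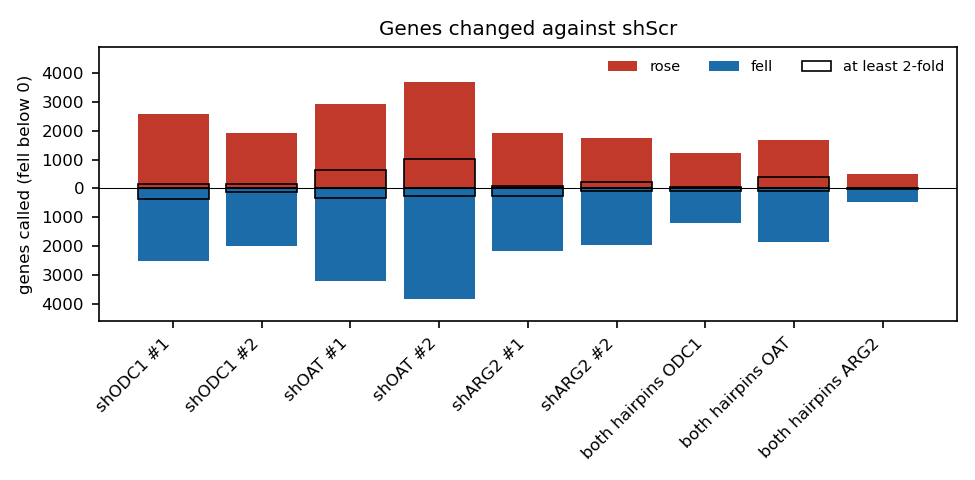
Genes called per hairpin against shScr, and with both hairpins of a target, with rises above 0 and falls below 0, and outlined bars for changes of at least 2-fold. Both hairpins called 2418 genes with ODC1, 3536 with OAT and 983 with ARG2.

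Knockdown of OAT was compared with shScr because the study asks whether OAT supplies polyamine synthesis in pancreatic cancer. REG4, a secreted lectin of the gut epithelium, rose from 1.70 ± 0.349 to 75.8 ± 3.49 and 95.2 ± 1.26 CPM, and CREB3L1, a membrane-bound transcription factor, from 0.898 ± 0.113 to 24.2 ± 7.24 and 23.8 ± 1.83 CPM. C2orf72, a gene of unknown function, rose from 1.22 ± 0.0452 to 41.9 ± 7.56 and 30.9 ± 1.61 CPM. ADAM19, a membrane metalloprotease, fell from 109 ± 10.4 to 12.2 ± 0.855 and 34.2 ± 1.64 CPM, and KLK6, a secreted serine protease, from 91.1 ± 3.19 to 26.4 ± 1.85 and 26.6 ± 1.21 CPM. In edgeR, REG4 rose by 5.48 ± 0.14 (SE; adjusted p = 6.71e-20) and 5.81 ± 0.14 (adjusted p = 3.96e-20), CREB3L1 by 4.74 ± 0.21 (adjusted p = 3.06e-15) and 4.72 ± 0.21 (adjusted p = 3.28e-15), and C2orf72 by 5.10 ± 0.17 (adjusted p = 7.36e-18) and 4.66 ± 0.17 (adjusted p = 4.42e-17). ADAM19 changed by -3.16 ± 0.08 (adjusted p = 1.46e-19) and -1.67 ± 0.08 (adjusted p = 3.31e-15), and KLK6 by -1.79 ± 0.07 (adjusted p = 4.49e-16) and -1.78 ± 0.07 (adjusted p = 3.94e-16). The matrix protein THBS1 rose by 2.44 ± 0.16 (adjusted p = 6.01e-12) and 3.75 ± 0.16 (adjusted p = 8.64e-16). Also up were ANK3 (2.91 and 2.72) and SCARA3 (2.61 and 4.09), and also down were ARHGEF4 (-2.58 and -2.15), KLK7 (-1.91 and -2.01) and EPHB2 (-2.06 and -1.77). EGR1, an early-response factor, was called down (-1.76 and -1.76) but not without shScr replicate 3 (-0.15 and -0.15, adjusted p = 0.627 and 0.591). Hairpin #1 called 6118 genes (2912 up, 3206 down) and hairpin #2 called 7531 (3702 up, 3829 down). Both called 3536 with the same sign, 1671 up and 1865 down, and of those that changed at least 2-fold 398 rose and 83 fell. With no normalization factors hairpin #2 called 4377 up and 3108 down, and both hairpins 1811 and 1647.

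Some arginine and polyamine genes fell with OAT knockdown. SLC7A1, the main arginine importer, fell from 222 ± 6.26 to 145 ± 10.4 and 122 ± 5.03 CPM (-0.62 and -0.87). SLC25A15, the mitochondrial ornithine carrier, fell (-0.51 and -0.45), as did the glutamate dehydrogenase gene GLUD1 (-0.24 and -1.02). Among polyamine genes the synthases SRM (-0.22 and -0.47) and SMS (-0.19 and -0.48), the salvage enzyme MTAP (-0.37 and -0.86) and the antizyme inhibitor AZIN1 (-0.27 and -0.71) fell, while the polyamine exporter of lysosomes ATP13A2 rose (0.42 and 0.42). AMD1 rose by 0.31 (edgeR adjusted p = 2.95e-06) and 0.12 (adjusted p = 0.0210), and the second call was lost without shScr replicate 1 (0.12, adjusted p = 0.0561) or 2 (0.09, adjusted p = 0.156) and without shOAT #2 replicate 1 (0.12, adjusted p = 0.0528) or 3 (0.11, adjusted p = 0.0646). The polyamine list had 2 of 21 up and 6 down (mean -0.14, camera adjusted p = 0.237), and the arginine list, OAT included, 6 of 16 down and none up (mean -0.44, adjusted p = 0.138).

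DNA replication and ribosome biogenesis genes fell with OAT knockdown. CDC45, a part of the replicative helicase, fell from 39.0 ± 0.656 to 25.6 ± 1.19 and 25.2 ± 0.976 CPM (-0.60 and -0.63), with the chromatin assembly gene CHAF1B (-0.79 and -0.56), GINS3 (-0.84 and -0.56) and the licensing factor CDT1 (-0.52 and -0.57). LYAR, a nucleolar factor, fell from 71.5 ± 2.83 to 37.1 ± 3.05 and 42.4 ± 1.87 CPM (-0.95 and -0.75), with RRP9 (-0.61 and -0.59), UTP4 (-0.56 and -0.54) and NOLC1 (-0.44 and -0.50) of ribosome biogenesis. In the DNA replication list 33 of 45 genes fell and none rose, or 34 adjusted over the list alone, with a mean of -0.35 (camera adjusted p = 7.48e-10). In the MYC and ribosome biogenesis list 28 of 39 fell and none rose, or 29 adjusted over the list alone, with a mean of -0.33 (adjusted p = 5.50e-10). Of the ribosomal protein genes, whose reads can be shared with pseudogenes, 10 of 54 fell and none rose, or 7 adjusted over the list alone, RPS7 (-0.23 and -0.50) and RPS2 (-0.16 and -0.32) among them (mean -0.20, adjusted p = 1.10e-06; adjusted p = 0.550 with an estimated correlation). That list call came from hairpin #2 (-0.37, adjusted p = 5.25e-11), since hairpin #1 alone did not pass (-0.03, adjusted p = 0.431) and the hairpins differed (adjusted p = 2.34e-11; adjusted p = 0.392 with an estimated correlation). In mitosis KIF20A rose (0.41 and 0.39) and MAD2L1 (-0.50 and -0.26), AURKB (-0.36 and -0.26) and CDC20 (-0.24 and -0.41) fell, with 1 of 43 up and 8 down, or 2 and 8 adjusted over the list alone (mean -0.01, adjusted p = 0.849). Among histone genes 1 of 23 rose and none fell (mean 0.34, adjusted p = 0.479), and adjusted over the list alone edgeR called 0. Chromatin regulators had 5 of 46 up, HDAC9 (1.87 and 1.10) and KAT2B (0.92 and 0.83) among them, and 4 down, with KDM1A (-0.56 and -0.27) and HDAC2 (-0.31 and -0.33) among them (mean 0.12, adjusted p = 0.533).

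The ATF4 response fell with OAT knockdown as well. DDIT4 fell from 253 ± 11.3 to 89.5 ± 8.94 and 85.4 ± 1.56 CPM, a change of -1.50 ± 0.09 (SE; edgeR adjusted p = 2.67e-11) and -1.56 ± 0.09 (adjusted p = 1.37e-11). SLC7A11 (-1.08 and -0.92), the glycine transporter SLC6A9 (-0.93 and -1.27) and the folate enzyme MTHFD2 (-0.75 and -0.99) fell too. In the ATF4 list 18 of 29 genes fell and none rose, with a mean of -0.43 (camera adjusted p = 8.82e-07). In the unfolded protein response HERPUD1 (0.56 and 0.32) and ERN1 (0.25 and 0.32) rose and SEC24D fell (-0.34 and -0.35), with 3 of 24 up and 3 down (mean -0.02, adjusted p = 0.904). The p53 targets BTG2 (2.26 and 1.62), TP53INP1 (1.53 and 1.78) and CDKN1A (0.77 and 0.75) rose and PHLDA3 fell (-1.22 and -1.04), with 5 of 28 up and 4 down (mean 0.08, adjusted p = 0.904). The oxidative stress gene HMOX1 (1.89 and 0.90) rose, as did AKR1B10 (3.85 and 2.01), whose reads can be shared with related genes, and the NRF2 and redox list had 7 of 26 up and 5 down (mean 0.19, adjusted p = 0.829).

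Transcripts of the mitochondrial genome rose with OAT knockdown. MT-ND5, a subunit of complex I, went from 324 ± 13.3 to 725 ± 52.5 and 861 ± 75.7 CPM (1.16 and 1.41), and MT-ND6 (1.28 and 1.55) and MT-CYB (0.95 and 0.92) rose as well, though nuclear copies of this genome can share such reads. Nuclear genes of the respiratory chain were not called as a list, with 1 of 42 down, UQCRC2 (-0.25 and -0.42), and none up (mean -0.02, camera adjusted p = 0.540). Of the 13 mitochondrial transcripts 12 rose and none fell, with a mean of 0.94 (adjusted p = 4.64e-06; adjusted p = 0.364 with an estimated correlation), and their share of all counts was 1.88% and 1.81% against 0.960% in shScr. In cholesterol metabolism ACAT2 (-0.30 and -1.14) and SREBF2 (-0.44 and -0.26) fell, with 7 of 25 down and none up, or 6 adjusted over the list alone (mean -0.24, adjusted p = 0.000311; adjusted p = 0.169 with an estimated correlation). That call too came from hairpin #2 (-0.43, adjusted p = 2.42e-07), with -0.05 for hairpin #1 (adjusted p = 0.635) and a difference between them (adjusted p = 2.21e-06; adjusted p = 0.101 with an estimated correlation). LPIN1 fell (-0.37 and -1.11) in the fatty acid list, which had 1 of 15 up and 2 down (mean -0.16, adjusted p = 0.128). The carbonic anhydrases CA9 (1.10 and 1.83) and CA12 (1.18 and 0.48) rose and ALDOC fell (-0.85 and -1.01), with 3 of 34 hypoxia and glycolysis genes up and 11 down (mean -0.07, adjusted p = 0.128).

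Several interferon genes, chemokines and epithelial genes rose with OAT knockdown. BST2, which tethers viruses to the cell surface, rose from 21.6 ± 1.35 to 42.2 ± 3.46 and 58.6 ± 1.89 CPM (0.97 and 1.44), with SAMD9L (1.51 and 1.77), IFI6 (1.34 and 1.34) and IFIT3 (0.65 and 0.86). The neutrophil chemokines CXCL1 (1.52 and 1.61), CXCL5 (1.37 and 2.06) and CXCL8 (0.96 and 1.69) and the adhesion gene ICAM1 (1.55 and 1.11) rose. The trefoil factor TFF1 rose from 0.128 CPM to 3.27 ± 0.644 and 3.53 ± 0.260 CPM (4.62 and 4.73), and TFF2 rose too (4.03 and 2.62), both from very few counts, whereas CEACAM5 fell (-1.34 and -0.79). The interferon list had 12 of 32 up and none down, or 14 adjusted over the list alone, with a mean of 0.45 (camera adjusted p = 0.000414). The classical epithelial list, REG4 included, had 18 of 34 up and 5 down, with a mean of 0.94 (adjusted p = 0.00238; adjusted p = 0.203 with an estimated correlation), and did not pass with hairpin #2 alone (0.73, adjusted p = 0.120). The NF-kB list had 7 of 23 up and none down (mean 0.44, adjusted p = 0.115).

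Other signalling and identity genes went both ways with OAT knockdown. The EGF-like ligand AREG (-1.12 and -0.88) and FOSL1 (-0.88 and -1.55) fell. The MAPK inhibitor SPRY1 rose (0.41 and 1.22). The lysosomal proteases CTSB (0.69 and 0.74), CTSD (0.78 and 0.54) and CTSA (0.75 and 0.55) rose, as did PSAP (0.52 and 0.49). CCN2, a target of YAP, rose (1.15 and 1.28) and PLAU fell (-2.44 and -0.55). Among basal-like genes KRT16 (1.59 and 1.40) and CTSV (1.53 and 1.22) rose and FGFBP1 fell (-0.59 and -1.0). The MAPK list had 3 of 30 up and 9 down (mean -0.23, camera adjusted p = 0.0772) and passed without shScr replicate 1 (-0.33, adjusted p = 0.00598) or 2 (-0.32, adjusted p = 0.0243). The lysosome list had 7 of 31 up and 2 down, or 7 and 3 adjusted over the list alone (mean 0.10, adjusted p = 0.128). The epithelial-mesenchymal list had 6 of 22 up and 4 down (mean 0.36, adjusted p = 0.852), and the basal-like list 3 of 13 up and 2 down (mean 0.26, adjusted p = 0.924). Among markers of other cell types 3 of 7 fibroblast genes rose and none fell, the proteoglycan gene LUM (0.93 and 1.07) among them (mean 1.08, adjusted p = 0.0661; 1.18 and adjusted p = 0.0392 without shScr replicate 1). Of 3 immune markers CD68 (0.21 and 0.21) rose and LYZ (-0.17 and -1.68), which also stands in the epithelial list, fell (mean -0.28, adjusted p = 0.716). Of 3 endothelial markers 1 rose, ESAM (1.43 and 1.5), and 1 fell (mean 0.43, adjusted p = 0.904). Camera called 8 of the 27 lists with OAT, and the DNA replication, MYC, ATF4 and interferon lists held with an estimated correlation (adjusted p = 0.0114, 0.00149, 0.0232 and 0.0117). The median, the mean and the test differed in sign for p53 targets and for the NRF2 and redox list.

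**Figure D3:**
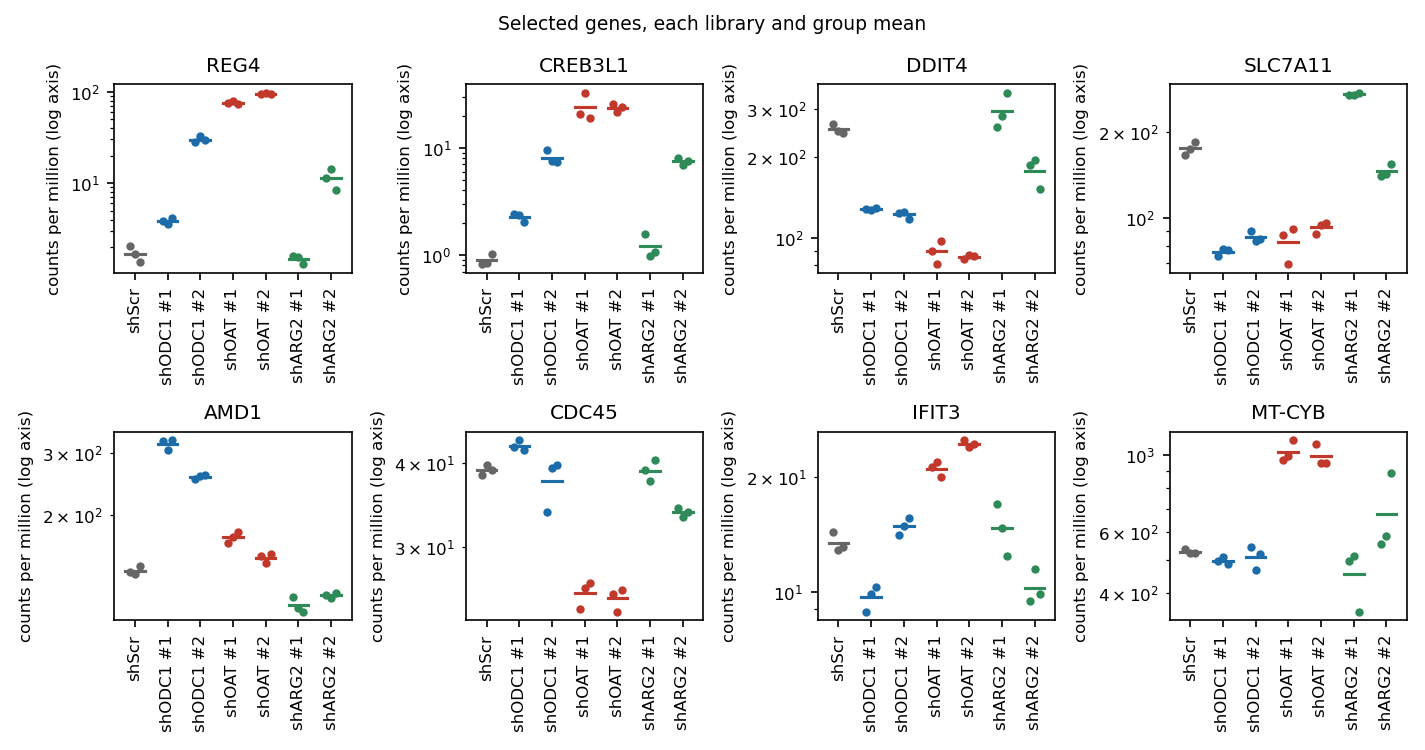
Levels of REG4, CREB3L1, DDIT4, SLC7A11, AMD1, CDC45, IFIT3 and MT-CYB in the 7 groups, in CPM on a log axis, with points for single libraries and lines for group means. REG4 stood at 1.70 CPM in shScr and at 75.8 and 95.2 CPM with the OAT hairpins.

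Knockdown of ARG2 was compared with shScr to test the other enzyme that yields ornithine. LRIG1, a brake on EGF receptors, rose from 3.71 ± 0.309 to 9.87 ± 0.412 and 35.4 ± 2.98 CPM, and LGR5, a stem cell receptor of the gut, from 11.4 ± 0.396 to 24.6 ± 3.24 and 31.8 ± 0.547 CPM. CEACAM5, an adhesion molecule of epithelial tumours, rose from 58.4 ± 5.83 to 119 ± 13 and 173 ± 2.60 CPM, and IGSF9B, a synaptic adhesion gene, from 3.75 ± 0.667 to 31.3 ± 3.63 and 15 ± 0.313 CPM. SEL1L3 fell from 43.3 ± 2.15 to 16.3 ± 1.19 and 19.7 ± 1.16 CPM, the transcription factor gene MYB from 19.0 ± 1.5 to 9.06 ± 0.507 and 7.67 ± 0.985, and the iron exporter gene SLC40A1 from 21.7 ± 3.68 to 10.6 ± 1.77 and 7.31 ± 1.40. In edgeR, LRIG1 rose by 1.41 ± 0.13 (SE; adjusted p = 1.94e-08) and 3.25 ± 0.13 (adjusted p = 3.95e-15), LGR5 by 1.12 ± 0.08 (adjusted p = 6.26e-10) and 1.48 ± 0.08 (adjusted p = 3.45e-12), and CEACAM5 by 1.02 ± 0.08 (adjusted p = 2.24e-09) and 1.56 ± 0.08 (adjusted p = 1.39e-12). IGSF9B rose by 3.06 ± 0.13 (adjusted p = 1.84e-14) and 1.99 ± 0.13 (adjusted p = 4.31e-11), the plasminogen activator PLAT by 1.19 ± 0.05 (adjusted p = 1.04e-14) and 0.81 ± 0.05 (adjusted p = 3.86e-12), and SEL1L3 changed by -1.41 ± 0.08 (adjusted p = 1.99e-12) and -1.14 ± 0.08 (adjusted p = 7.88e-11). Also up was MEF2C (1.59 and 0.85), and also down were AK4 (-1.49 and -1.28) and CDH3 (-1.81 and -1.05). EGR1 was called down (-1.62 and -2.07) but not without shScr replicate 3 (-0.01 and -0.44, adjusted p = 0.989 and 0.169). Hairpin #1 called 4101 genes (1930 up, 2171 down) and hairpin #2 called 3691 (1746 up, 1945 down). Both called 983 with the same sign, 496 up and 487 down, of which 24 and 26 changed at least 2-fold. With only the groups compared in the fit, hairpin #2 called 1746 genes and both hairpins 602. With ARG2 itself near the detection limit and called by 1 hairpin only, these changes cannot be tied to its level.

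A minority of DNA replication and ribosomal protein genes fell with ARG2 knockdown, and 3 polyamine genes were called. AMD1 fell from 140 ± 4.05 to 112 ± 5.57 and 119 ± 1.85 CPM, a change of -0.33 (edgeR adjusted p = 6.57e-06) and -0.23 (adjusted p = 0.000450), and the polyamine transporter ATP13A3 rose (0.53 and 0.21). The clamp loader RFC2 (-0.38 and -0.27) and CDC6 (-0.24 and -0.24) fell. In mitosis MKI67 rose (0.37 and 0.63) and MAD2L1 (-0.23 and -0.49) and CDK1 (-0.20 and -0.25) fell. LYAR (-0.73 and -0.36) and GNL3 (-0.22 and -0.29) of ribosome biogenesis fell, as did RPL13 (-0.27 and -0.24) and RPL9 (-0.21 and -0.26), whose reads can be shared with pseudogenes. The helicase of chromatin remodeling SMARCA4 rose (0.36 and 0.31). The polyamine list had 1 of 21 up and 2 down (mean -0.01, camera adjusted p = 0.904), and the arginine list 2 of 16 down and none up, or 1 up and 2 down adjusted over the list alone (mean -0.16, adjusted p = 0.321). The DNA replication list had 1 of 45 up and 6 down, with a mean of -0.10 (adjusted p = 0.00228; adjusted p = 0.181 with an estimated correlation), and the mitosis list 2 of 43 up and 3 down (mean 0.03, adjusted p = 0.657). Of ribosomal protein genes 15 of 54 fell and none rose, or 18 adjusted over the list alone, with a mean of -0.15 (adjusted p = 8.61e-09; adjusted p = 0.473 with an estimated correlation). The MYC list had 2 of 39 up and 5 down, or 2 and 6 adjusted over the list alone (mean -0.03, adjusted p = 0.596). Chromatin regulators had 7 of 46 up and 1 down, or 9 and 1 adjusted over the list alone. Their mean with all libraries was 0.10 (camera adjusted p = 0.00238, and adjusted p = 0.409 with an estimated correlation). Without shScr replicate 1 the mean was 0.06. edgeR called 0 of 23 histone genes, with 0 at unadjusted p under 0.05 and 0 with DESeq2 (mean 0.19, camera adjusted p = 0.583; -0.45 without shARG2 #2 replicate 3).

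Some genes of lipid synthesis, the respiratory chain and redox balance fell with ARG2 knockdown. The lipid genes STARD4 (-0.41 and -0.68) and FDFT1 (-0.36 and -0.22) of cholesterol metabolism and FADS2 (-0.93 and -0.66) and ELOVL5 (-0.26 and -0.48) of fatty acid synthesis fell. SDHD of complex II (-0.46 and -0.39) fell, and so did NQO1 (-0.41 and -0.26), TXN (-0.25 and -0.33) and the ferritin gene FTH1 (-0.25 and -0.24). KDM3A (0.57 and 0.36) and the lactate exporter SLC16A3 (0.36 and 0.37) rose while LDHA fell (-0.18 and -0.18). The cholesterol list had 1 of 25 up and 4 down, with a mean of -0.14 (camera adjusted p = 0.000994; adjusted p = 0.197 with an estimated correlation), and the fatty acid list 1 of 15 up and 4 down, or 1 and 5 adjusted over the list alone (mean -0.13, adjusted p = 0.108). Of the respiratory chain genes 5 of 42 fell and none rose, or 4 adjusted over the list alone, with a mean of -0.17 (adjusted p = 2.90e-06; adjusted p = 0.445 with an estimated correlation). The NRF2 and redox list had 1 of 26 up and 4 down, or 1 and 5 adjusted over the list alone. Its mean with all libraries was -0.12 (camera adjusted p = 0.00231, and adjusted p = 0.289 with an estimated correlation). Without shScr replicate 3 the mean was -0.08. The hypoxia and glycolysis list had 3 of 34 up and 4 down, or 3 and 5 adjusted over the list alone (mean -0.07, adjusted p = 0.479). edgeR called 0 of 13 mitochondrial transcripts, with 0 at unadjusted p under 0.05 and 0 with DESeq2 (mean 0.06, camera adjusted p = 0.829). It called 0 of 24 genes of the unfolded protein response, again with 0 at unadjusted p under 0.05 and 0 with DESeq2 (mean 0.02, camera adjusted p = 0.479). In the ATF4 list TRIB3 fell (-0.35 and -0.19), the only call among 29 genes, and its hairpin #2 call was lost without shScr replicate 3 (-0.12, adjusted p = 0.135) or shARG2 #2 replicate 1 (-0.16, adjusted p = 0.0792); the list itself did not pass (mean -0.05, adjusted p = 0.222).

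Signalling and identity lists did not pass with ARG2 knockdown. TNFAIP3, an inhibitor of NF-kB, rose (0.56 and 1.04) while CXCL5 (-0.49 and -0.77) and LCN2 (-0.22 and -0.42) fell. SAMD9 rose (0.49 and 0.69) and USP18, which removes ISG15, fell (-0.48 and -0.73), while the phosphatase gene DUSP4 rose (0.23 and 0.20). CEACAM5 rose and CLDN3 (-0.44 and -1.17) and EPCAM (-0.44 and -0.31) fell among epithelial genes, TNC rose (0.71 and 0.21) and TGFBI fell (-0.32 and -0.37) among mesenchymal genes, and the protease CTSS fell (-0.56 and -1.54). The interferon list had 1 of 32 up and 1 down (mean -0.07, camera adjusted p = 0.479), and the NF-kB list 1 of 23 up and 3 down, or 1 and 4 adjusted over the list alone (mean -0.01, adjusted p = 0.911). The MAPK list had 1 of 30 up and 1 down (mean -0.07, adjusted p = 0.904), and without shScr replicate 3 it passed in the other direction (0.13, adjusted p = 0.0441). The lysosome list had 1 of 31 up and 1 down (mean -0.04, adjusted p = 0.904), and in the p53 list 1 of 28 fell, CCNG1 (-0.25 and -0.30), and none rose (mean 0.03, adjusted p = 0.904). The epithelial-mesenchymal list had 1 of 22 up and 2 down, or 2 and 2 adjusted over the list alone (mean 0.12, adjusted p = 0.479), the epithelial list 3 of 34 up and 3 down, or 4 and 3 adjusted over the list alone (mean 0.20, adjusted p = 0.510), and the basal-like list 3 of 13 up and none down (mean 0.29, adjusted p = 0.196). edgeR called 0 of 7 fibroblast markers and 0 of 3 immune markers, with 0 of either at unadjusted p under 0.05 and 0 with DESeq2 (means 0.30 and 0.16, camera adjusted p = 0.904 for both), and 1 of 3 endothelial markers fell (mean 0.18, adjusted p = 0.998). Camera called 6 of the 27 lists, 1 up and 5 down, and none of them held with an estimated correlation. With hairpin #2 alone the DNA replication, cholesterol, respiratory chain and NRF2 lists did not pass (adjusted p = 0.0686, 0.420, 0.0796 and 0.116). With hairpin #1 alone the chromatin list did not (adjusted p = 0.0557). The median, the mean and the test differed in sign for the polyamine, NF-kB, basal-like, immune and endothelial lists.

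**Figure D4:**
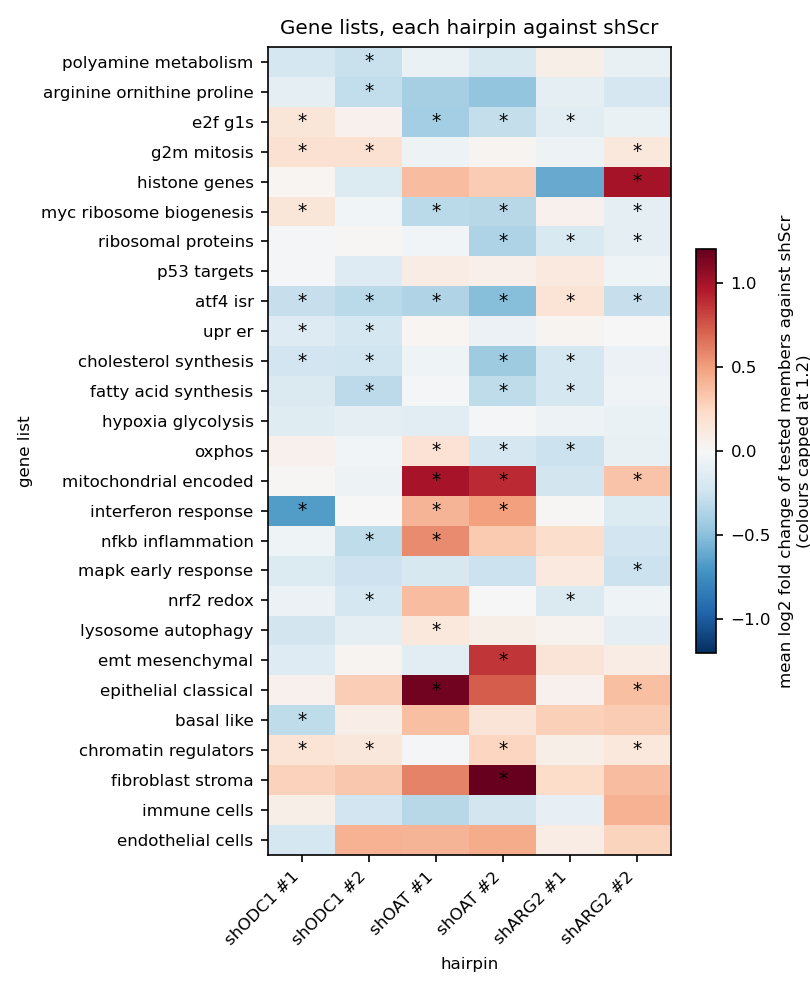
Mean log2 fold change of each gene list with each hairpin against shScr, with colours capped at 1.2 and an asterisk where camera with a preset correlation, run on that hairpin alone, gave an adjusted p under 0.05. The ATF4 list had a mean of -0.30 over the ODC1 hairpins and -0.43 over the OAT hairpins.

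The hairpins of a target were compared to learn how far their effects were shared. With OAT, the respiratory chain list had a mean of 0.17 with hairpin #1 and -0.21 with hairpin #2, and with ARG2 the ATF4 list had 0.17 and -0.28. The epithelial-mesenchymal list had -0.14 and 0.86 with OAT (camera adjusted p = 1.97e-05 for the difference; adjusted p = 0.116 with an estimated correlation). LRIG1 rose far more with shARG2 #2 than with shARG2 #1, at 35.4 ± 2.98 against 9.87 ± 0.412 CPM, and REG4 rose to 29.9 ± 2.33 CPM with shODC1 #2 but 3.83 ± 0.279 CPM with shODC1 #1. Of the genes called by both hairpins 93.7% had the same sign with ODC1 (2418 of 2581), 83.6% with OAT (3536 of 4229) and 65.5% with ARG2 (983 of 1500). Independent calls would give 790 genes with the same sign with ODC1, 1812 with OAT and 597 with ARG2. Across genes, which are not independent replicates, the fold changes of the hairpins correlated with r of 0.598 for ODC1, 0.637 for OAT and 0.159 for ARG2, but shared controls alone give a positive r. With no shScr library on both sides the mean r over 6 arrangements of the controls was 0.426, 0.520 and 0.0234, and for ARG2 it ran from -0.10 to 0.149. In direct tests between the hairpins of a target edgeR called 3164 genes with ODC1, 7163 with OAT and 5860 with ARG2, and 243, 919 and 700 of these differed at least 2-fold. With no normalization factors the genes that differed between the OAT hairpins were 2752 higher and 4385 lower with hairpin #1, against 3585 and 3578.

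Changes shared by ODC1 and OAT knockdown were counted to ask whether loss of OAT resembles loss of ODC1. REG4 rose with all 4 hairpins (1.17, 4.13, 5.48 and 5.81, ODC1 first), as did CREB3L1 (1.34, 3.17, 4.74 and 4.72), RFLNA (1.87, 1.85, 2.88 and 3.30), C2orf72 (1.62, 1.90, 5.10 and 4.66), the lipid kinase gene PIP5K1B (1.96, 1.23, 3.00 and 2.89) and LBH (1.57, 1.31, 2.95 and 1.83). DDIT4 fell with all 4 (-0.98, -1.04, -1.50 and -1.56), as did the kallikreins KLK6 (-1.34, -1.22, -1.79 and -1.78) and KLK8 (-0.99, -1.29, -1.42 and -1.97), the fucosyltransferase gene FUT8 (-1.24, -1.0, -1.73 and -1.26), HYAL1 (-1.59, -1.09, -1.16 and -1.43) and CHST2 (-2.41, -1.44, -1.29 and -1.67). In edgeR 471 genes rose and 494 fell with all 4 hairpins, where independent sets would share 162 and 174. Genes that moved in opposite directions with the 2 targets numbered 47 and 30. Across genes the mean fold changes of ODC1 and OAT correlated with r of 0.479 (Spearman rho of 0.448), and with r of 0.510 among the 8990 genes with a mean CPM of at least 10. Both targets share the shScr libraries, and unchanged groups simulated with the same controls gave r of 0.667 but a covariance of 0.0175, against 0.102 here. With the shScr libraries divided between the targets the covariance was 0.0803 (0.0664 to 0.0874 over 6 arrangements) and r was 0.333, and genes are not independent replicates.

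Fewer changes were shared with ARG2, and fewer genes were called with it. With all 6 hairpins the cilium gene TULP3 rose (1.21, 1.13, 0.90, 1.11, 1.09 and 1.28, in the order ODC1, OAT and ARG2), as did AHNAK2 (0.79, 1.09, 1.5, 1.5, 0.68 and 0.73) and the triglyceride synthesis gene DGAT2 (1.08, 1.67, 1.46, 1.82, 0.95 and 0.52). SEL1L3 fell with all 6 (-0.82, -1.19, -0.69, -1.38, -1.41 and -1.14), as did the ligand gene TNFSF9 (-0.83, -1.03, -0.75, -0.57, -0.94 and -0.67), LONRF1 (-0.68, -1.08, -1.04, -1.27, -0.51 and -1.0) and CTSS (-1.62, -1.51, -0.62, -0.57, -0.56 and -1.54). UGT1A1 (0.96, 0.92, 1.34, 1.06, 1.08 and 0.97) and UGT1A10 (0.92, 1.26, 1.62, 1.28, 0.58 and 0.75) were called up too, but they share exons, so which of them changed is uncertain. In edgeR 76 genes rose and 55 fell with all 6 hairpins, where independent sets would share 6.30 and 6.66. With other groups as the reference 154 to 2148 genes were alike. In 20 simulated fits edgeR called 0 with all 6 hairpins or all 4 of ODC1 and OAT. With no true change these fits cannot weigh a shared reference. ODC1 and ARG2 knockdown shared 180 rises and 136 falls, where independent sets would share 48.0 and 45.4. OAT and ARG2 knockdown shared 154 and 143, against 65.1 and 71.4. Opposite changes of ODC1 and ARG2 numbered 12 and 13, and of OAT and ARG2 43 and 47. Across genes r was 0.358 for ODC1 and ARG2 and 0.235 for OAT and ARG2. Covariances were 0.0407 and 0.0412 against 0.0175 and 0.0174 in the simulation. With the shScr libraries divided these were 0.0188 and 0.0194 (-0.00594 to 0.0341 and -0.00332 to 0.0344). A covariance with ARG2 beyond the shared controls was therefore not certain. With single ODC1 and OAT hairpins, r was then -0.114 to 0.0198 for shARG2 #1 and 0.158 to 0.271 for shARG2 #2.

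OAT and ODC1 knockdown were then set against each other to find where they differ. REG4 was higher with OAT knockdown by 2.99 ± 0.08 (SE; edgeR adjusted p = 8.43e-20), C2orf72 by 3.12 ± 0.10 (adjusted p = 2.97e-18), the bradykinin receptor gene BDKRB2 by 2.85 ± 0.10 (adjusted p = 1.50e-17), and the connexin gene GJB1 by 2.61 ± 0.11 (adjusted p = 7.83e-16). IGSF9B was lower with OAT knockdown (-2.78 ± 0.10, adjusted p = 5.96e-17), and so were ADAM19 (-2.04 ± 0.06, adjusted p = 1.85e-19) and OAT itself (-3.24 ± 0.08, adjusted p = 5.33e-21). DNA replication genes were lower with OAT than with ODC1 knockdown by a mean of -0.44 (camera adjusted p = 7.05e-15; 0.000718 with an estimated correlation), and MYC and ribosome biogenesis genes by -0.38 (adjusted p = 1.31e-13; 0.000195). Interferon genes were higher by a mean of 0.79 (adjusted p = 7.95e-09; 0.000195 with an estimated correlation), NF-kB genes by 0.62 (adjusted p = 0.00119; 0.0199), lysosomal genes by 0.27 (adjusted p = 5.85e-05; 0.00856) and classical epithelial genes by 0.77 (adjusted p = 2.07e-05; 0.0463). The mitochondrial transcripts were higher by 0.96 (adjusted p = 1.48e-06; adjusted p = 0.307 with an estimated correlation). The polyamine list did not differ detectably (0.11, adjusted p = 0.980). The count of genes was 5250, with 2604 higher and 2646 lower with OAT knockdown, of which 750 and 93 differed at least 2-fold. With no normalization factors it was 3156 and 2036, so the balance of directions depended on the scaling.

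ARG2 knockdown was set against the other 2 targets in the same way. LRIG1 was higher with ARG2 than with ODC1 knockdown by 2.06 ± 0.09 (SE; edgeR adjusted p = 8.06e-15), and ODC1 by 1.88 ± 0.03 (adjusted p = 1.82e-23). C2orf72 was lower (-2.12 ± 0.15, adjusted p = 5.26e-11), as was SLC40A1 (-1.80 ± 0.11, adjusted p = 4.45e-11). Against OAT knockdown, IGSF9B was higher by 3.52 ± 0.10 (adjusted p = 2.23e-19), ADAM19 by 2.68 ± 0.06 (adjusted p = 6.64e-22) and CEACAM5 by 2.36 ± 0.06 (adjusted p = 1.01e-19). REG4 was lower (-4.36 ± 0.09, adjusted p = 4.27e-22). DNA replication genes were lower with ARG2 than with ODC1 knockdown by a mean of -0.20 (camera adjusted p = 1.48e-06; 0.0191 with an estimated correlation) and higher than with OAT knockdown by 0.25 (adjusted p = 5.20e-07; 0.0153). ATF4 genes were higher with ARG2 than with OAT knockdown by 0.38 (adjusted p = 1.79e-05; 0.0312), and higher than with ODC1 knockdown by 0.25 (adjusted p = 0.000603; adjusted p = 0.0906 with an estimated correlation). The ARG2 side of both pooled hairpins of opposite sign (0.17 and -0.28), and the second was like ODC1 knockdown (-0.28 and -0.33). MYC genes were higher with ARG2 than with OAT knockdown by 0.30 (adjusted p = 2.92e-09; 0.000718) and interferon genes lower (-0.52, adjusted p = 3.13e-05; 0.00222). ARG2 and ODC1 knockdown differed in 4609 genes, 2123 higher and 2486 lower with ARG2, and ARG2 and OAT knockdown differed in 5174, 2626 higher and 2548 lower. With no normalization factors the first was 2451 higher and 2140 lower and the second 2347 and 2728, so both balances turned.

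ATAC-seq was compared between groups to ask whether the knockdowns changed open chromatin. Each target gene had a region at 1 of its ends with a peak in all 14 libraries: chromosome 2, 10447546 to 10449275 at ODC1, chromosome 10, 124418242 to 124419488 at OAT, and chromosome 14, 67619397 to 67620252 at ARG2, where it also overlaps GPHN. The peaks of all libraries merged into 100412 regions, of which 46463 (46.3%) held a peak in all 14 libraries and 15225 (15.2%) in 1. The shScr libraries had a mean of 69996 peaks, and the knockdowns differed from it by 1648 with ODC1, -2130 with OAT and -552 with ARG2 (exact permutation p = 0.8, 0.667 and 0.933, 2-sided, where the smallest p possible is 0.0667). Their signs depended on which shScr library was left out. Pairs of libraries had a Jaccard index of 0.672 to 0.768. Replicates of a group had 0.738 against 0.729 in other pairs (permutation p = 0.0584, 1-sided). This passed with lists of equal length (0.756 against 0.743, permutation p = 0.0028). Libraries of the same target had 0.737 against 0.728 (permutation p = 0.025).

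With the full peak lists no target lost or gained more regions than the highest of the other divisions of the same libraries. A region near C2orf72, a gene that rose with OAT, was gained with OAT and ARG2 (chromosome 2, 231050323 to 231050826). It held a peak in 11 libraries. A region within 1 kb of SEL1L3 (chromosome 4, 25863487 to 25863707) was lost with ODC1 and OAT, and one near CTSS (chromosome 1, 150765616 to 150766049) with OAT. Other losses with OAT included a region in ALK (chromosome 2, 29749035 to 29749395), and gains one in SEMA3D (chromosome 7, 85025236 to 85025718) and one at SULT1E1 (chromosome 4, 69832512 to 69832987). ARG2 knockdown lost regions in RNF130 (chromosome 5, 179967478 to 179967825) and CTNNA3 (chromosome 10, 67259192 to 67259871), and ODC1 knockdown one in LHFPL2 (chromosome 5, 78527170 to 78527309). With ODC1 316 regions were lost and 435 gained, with OAT 663 and 349, and with ARG2 497 and 442. Of the 15 divisions of the 6 libraries into 2 and 4, the real one included, 10 and 4 gave as many for ODC1, 4 and 6 for OAT, and 6 and 4 for ARG2. With lists of equal length the real division was the highest for OAT, with 697 lost and 580 gained against 622 and 466 at most in the others, and for ARG2 gains, with 521 against 424, though 15 divisions cannot give a share under 0.0667. Counts of lost plus gained regions rose with any library left out.

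**Figure D5:**
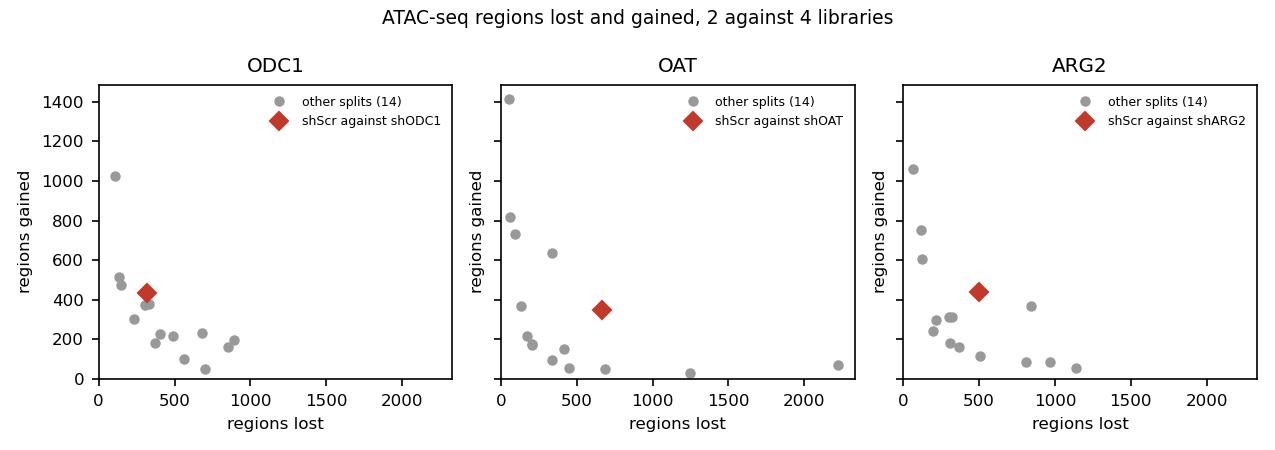
Number of regions lost and gained with each target against shScr, for the real division of the 6 libraries (red diamonds) and the 14 other divisions (grey points). With OAT, 663 regions were lost and 349 gained, while other divisions reached 2221 and 1416.

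Lost and gained regions were joined to genes within 1 kb to ask whether expression followed chromatin. Near regions gained with OAT knockdown 5 of 10 genes rose, and near regions lost with ARG2 knockdown 5 of 28 genes fell. Near regions lost with ODC1 knockdown 5 of 19 genes fell, and with OAT knockdown 11 of 43. The odds ratio was 6.89 for OAT gains and 5.32 for ARG2 losses (Fisher's exact test p = 0.00476 and 0.00441, adjusted p = 0.0143 for both). For ODC1 losses it was 3.32 (Fisher's exact test p = 0.0317, adjusted p = 0.0633), and the other 3 combinations did not pass, with odds ratios of 1.90 for OAT losses, 1.28 for ODC1 gains and 3.05 for ARG2 gains (adjusted p = 0.128, 0.671 and 0.189). Within 5 kb the odds ratios were 3.35 for OAT gains and 2.66 for ARG2 losses, and ODC1 losses (2.04) and ARG2 gains (2.57) then passed too (adjusted p = 0.0398 for both, Fisher's exact test). With the full peak lists the numbers of lost and gained regions did not exceed those of other divisions, so the ratios rest on few genes near regions of uncertain change.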

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

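The patterns and the outlying libraries were seen in the data first; the tests of single-hairpin effects, of a response to ARG2 loss, and of RNA from fibroblasts, immune or endothelial cells were chosen after their results were seen, no normalization factors after the data were seen, and the other tests before their results.

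Knockdown of ARG2 changed 4101 genes with hairpin #1 and 3691 with hairpin #2, but LRIG1, CEACAM5, LGR5 and the other genes changed alike numbered only 983, while 517 genes were called with opposite signs. The outlying library shARG2 #2 replicate 3 was argued against as the cause, since without it the fold changes of both hairpins still correlated across genes with r of 0.209, with 1064 genes of the same sign and 614 of opposite sign. Effects of single hairpins or of the cells that carry them may contribute, since with no shScr library on both sides r between the ARG2 hairpins was 0.0234 (0.159 with all controls on both sides), while an ARG2 and an ODC1 hairpin reached 0.271. A response to ARG2 loss cannot be told apart from noise in the controls: the ARG2 pair's covariance of 0.0246 lay above the highest of 100 simulations of unchanged groups (0.0193) but ran from -0.0221 to 0.0258 with no shScr library on both sides, and an ARG2 hairpin had 0.0927 with a hairpin of another target. Chance cannot be excluded for the ARG2 count: 6 of 100 divisions of the 9 libraries gave as many genes, with 602 genes for the real one and 1325 for the highest other.

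TULP3, AHNAK2 and DGAT2 rose and SEL1L3, CTSS and TNFSF9 fell with every hairpin, among 131 genes changed alike in all 6. The outlying library shScr replicate 3 was argued against as the cause, since 125 genes (78 up, 47 down) were called alike in all 6 hairpins without it. What stays open is the shared reference, since each of the other 6 groups, taken as the reference in place of shScr, gave 154 to 2148 such genes. The 131 genes may therefore reflect how the shScr libraries differ from the rest as much as a response to hairpins against this pathway. A biological response common to the 3 targets was not tested further.

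Of the genes that changed at least 2-fold with both OAT hairpins, REG4, CREB3L1 and C2orf72 among them, 82.7% rose (398 up, 83 down). Normalization was argued against, since the lowest share with other or no normalization factors was 83.3%. Among genes with a mean CPM of at least 10 over all libraries the share of rises was 70.5% (79 up, 33 down). That mean includes the OAT libraries, so genes low in shScr, such as REG4 and C2orf72, can pass because they rose. The share therefore cannot decide whether low counts in the control are the cause. RNA of fibroblasts, immune cells or endothelial cells was argued against, since the highest level of COL1A1, COL1A2, COL3A1, PTPRC or PECAM1 in an OAT knockdown library was 1.18 CPM, although LUM rose from 176 to 362 CPM. RNA of other epithelial cells was not tested, and a biological response to OAT loss stays open as a hypothesis, found and tested on the same data.

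Hairpins of the same target moved 163 genes in opposite directions with ODC1 and 693 with OAT, in tests of each hairpin and of their difference. The respiratory chain list differed by 0.37 between the OAT hairpins (0.17 with #1 and -0.21 with #2; camera adjusted p = 2.49e-07 for the difference, 0.367 with an estimated correlation). The ATF4 list differed by 0.44 between the ARG2 hairpins (0.17 with #1 and -0.28 with #2; adjusted p = 6.33e-07, 0.0376 with an estimated correlation). The DNA replication list, which holds CDC45, had a mean of 0.10 with ODC1 and -0.35 with OAT, a difference of -0.44 (adjusted p = 7.05e-15). The interferon list, which holds IFIT3, went down with ODC1 and up with OAT, a difference of 0.79 (adjusted p = 7.95e-09), although the fall with ODC1 was in hairpin #1 (-0.67) and not in hairpin #2 (-0.00418). The DNA replication list had a mean of -0.10 with ARG2 and 0.10 with ODC1, a difference of -0.20 (adjusted p = 1.48e-06, 0.0191 with an estimated correlation), while neither target's own call held with an estimated correlation (adjusted p = 0.181 and 0.321).

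For the genes that changed with both hairpins of ODC1 and of OAT, 1 of 100 divisions of the same libraries, the real one, gave as many. The same held for the 3 differences between targets. This argues against a chance division of single libraries. The divisions broke up the replicates of a hairpin, so they cannot exclude differences between hairpins that do not come from the target. The real and the highest other count were 2929 and 1692 for ODC1, 3476 and 2487 for OAT, 5386 and 1272 for OAT against ODC1, 4477 and 22 for ARG2 against ODC1, and 5016 and 2699 for ARG2 against OAT. These counts come from fits of the groups compared alone. For 3 libraries against 3 the 10 divisions are too few for a share under 0.05. There the real counts were 5158 and 4238 for the ODC1 hairpins, 5256 and 7804 for OAT, and 3827 and 1746 for ARG2, and 4574, 7226 and 4422 between the hairpins of ODC1, OAT and ARG2, while the highest other count was 0 in each with edgeR.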

How the results depend on the processing

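Leaving out the 3 outlying libraries together (shScr replicate 3, shOAT #1 replicate 2 and shARG2 #2 replicate 3), using no normalization factors, dividing the shScr libraries between the targets, and measuring the 1 and 5 kb, distances fixed before, from gene ends in place of transcription start sites were chosen after seeing the data. The other alternatives were chosen before.

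Most results held. Of the values of named genes with a library left out, 5005 of 5304 kept their call or lack of it, 296 lost a call, 3 gained one and none reversed; with DESeq2 846 of 849 were kept, with its size factors 851 of 854, with no filter 833 of 854, and with only the groups compared 793 of 849. Of the list results, 717 of 729 held with a library left out and 66 of 81 with an estimated correlation, and all 81 held with a prior count of 0.5 and with a replicate block. Genes changed with both hairpins ranged from 1721 to 3712 for ODC1, 3010 to 3660 for OAT and 602 to 1180 for ARG2. The median of all genes was at most 0.0692 from 0 with any scaling, for shOAT #2 with no factors. The numbers of the replicates do not pair the libraries: same-number pairs of different groups had a mean r of -0.00614, and with a replicate block both hairpins called 2376, 3498 and 937 genes. A mean CPM of at least 1 gave no value for ARG2, whose level is below it. Depth limits ARG2, TFF1 and TFF2, which rest on few counts, and the unknown ATAC-seq depth limits peak numbers and lost or gained regions.

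With a log2 fold change of at least 1 the counts were 502 and 294 for the ODC1 hairpins, 978 and 1287 for OAT, 346 and 326 for ARG2, and 130, 481 and 50 for both hairpins of each. They were 843, 350 and 895 for OAT against ODC1, ARG2 against ODC1 and ARG2 against OAT, and 243, 919 and 700 between the hairpins of ODC1, OAT and ARG2, all fewer by construction. With only the groups compared shARG2 #2 called 1746 genes (991 up, 755 down) and both ARG2 hairpins 602; the cause was not tested. An estimated correlation left 3, 4 and 0 list calls for ODC1, OAT and ARG2. With a hairpin alone the respiratory chain with shOAT #1 (0.17) and ATF4 with shARG2 #1 (0.17) reversed, and interferon with shODC1 #2 came close to 0 (-0.00418); the cause was not tested. Without the 3 outlying libraries both ODC1 hairpins called 3712 genes, FOS with shOAT #1 was at 0.0154 (adjusted p = 0.923), ARG2 with shARG2 #2 at -2.42 (adjusted p = 0.00510), and the MAPK list with ARG2 at 0.15 (adjusted p = 0.0120). Single pairs of ODC1 and OAT hairpins correlated with r of 0.296, 0.361, 0.376 and 0.523, and with the shScr libraries divided between the targets r was 0.333, as no control is then shared. With each library left out, ARG2 ranged from -2.29 to -1.39 with shARG2 #1 and from -2.21 to -0.88 with shARG2 #2, and the MAPK list with ARG2 from -0.17 to 0.13, the highest without shScr replicate 3.

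For ATAC-seq with lists of equal length, replicates of a group were more alike by a Jaccard index of 0.0127 (permutation p = 0.0028), and same-number libraries by 0.000472 (permutation p = 0.351). Regions lost or gained numbered 1191, 1537 and 1750 with ODC1, OAT and ARG2 when a peak had to cover 50% of a region, and 2636, 3455 and 3168 when 1 of 4 libraries was allowed to differ. Within 5 kb of a gene end, regions gained with ARG2 and rises had an odds ratio of 2.57 (Fisher's exact test p = 0.0263). With each library left out the difference in peak number ranged from -3357 to 6652 for ODC1, -7134 to 2875 for OAT and -5557 to 4453 for ARG2, lowest without shScr replicate 2 and highest without shScr replicate 1. Lost and gained regions then ranged from 1141 to 4495, 1399 to 5516 and 1322 to 5471, each highest without shScr replicate 2, and lowest without shODC1 #1 replicate 2, shOAT #1 replicate 2 and shARG2 #2 replicate 2. They are higher by construction, since fewer libraries have to concur.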

Other observations

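The levels of an iron exporter and a stem cell receptor differed between the targets. SLC40A1, the iron exporter, stood at 21.7 ± 3.68 CPM in shScr, at 96.0 ± 18.2 and 79.9 ± 2.60 with the OAT hairpins, and at 10.6 ± 1.77 and 7.31 ± 1.40 with the ARG2 hairpins. LGR5 was at 11.4 ± 0.396 CPM in shScr and reached 53.1 and 84.7 CPM with the OAT hairpins, above its levels with the ARG2 hairpins (24.6 ± 3.24 and 31.8 ± 0.547). No explanation was tested for these levels.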
